A study of Arabidopsis thaliana with 10 samples.

How the data were processed

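Total RNA from whole seedlings of Arabidopsis thaliana, ecotype Columbia-0, was hybridised to 10 Agilent arrays with a single dye (Cy3). Seedlings aged 14 days received 200 Gy of gamma radiation over 4 h, a rate of 50 Gy per h, or a mock treatment, and were sampled at 24 h. The experiment was run 5 times on different days with independent plants, per the labels, and each run gave 1 mock and 1 gamma array. Experiments 1 and 2 were run in an earlier year than experiments 3, 4 and 5, per the sample titles.

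The scanner files hold linear spot intensity, per the file headers: background-subtracted and detrended processed signals, and the median pixel brightness of each spot and of its local background, all from Agilent Feature Extraction 11.0.1.1. The submitters' processing notes name version 9.1 of that software instead. No scaling between arrays is recorded in the headers. Each array held 43803 non-control spots for 43603 probes; 71.7% to 76.6% of the probes were well above background and 0 spots were saturated. The number of arrays limits the precision of every estimate.

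The deposited value table holds linear ratios, as the comparison with the scanner values showed. Across probes, which are not independent replicates, each of its columns followed that array's probe-centred log2 processed signal with r of at least 0.997, so the scale is linear and higher means brighter. The median over the arrays was 1, within 1e-04, for 77.7% of probes, so most rows were centred on that median. The centring of the remaining rows and the scaling between arrays stay unknown. Its column medians were 0.969, 0.963, 0.959, 0.974 and 0.9255 for mock arrays 1 to 5, and 0.967, 0.960, 0.967, 0.9925 and 0.925 for gamma arrays 1 to 5. The table was used only as an alternative.

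Values were analysed as log2 of the processed signal minus each array's 75th percentile of it, after control spots and spots marked as outliers by the software were left out, and replicate spots of a probe were averaged. Probes were named through their transcript accessions with the RefSeq gene table of assembly TAIR10.1: 34348 probes matched a locus and 9255 did not and kept the array's own identifier. The array grid names TAIR10 as its build, so no coordinates are given and loci are named by their Arabidopsis locus codes. Of the probes of a gene, the brightest on average was used. Probes had to be well above background on at least 5 of the 10 arrays, which left 23666 genes, 20037 of them with a locus code.

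Gamma was compared with mock in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), two-sided, with the experiment as a fixed block and Benjamini-Hochberg adjustment at 0.05. The pairing comes from the run given in the titles and the stated repetition on different days. The deviations of mock and gamma arrays from their group means correlated within each experiment, at 0.737, 0.562, 0.775, 0.739 and 0.894 across genes in experiments 1 to 5, and every array correlated best with its partner. The residual degrees of freedom were 4 and the prior added 2.27. Where a gene was not well above background on any array of a group, its fold is given as a bound: the mean of the brighter group against the mean, in the dimmer group, of the higher of the gene's own signal and the lowest signal among probes well above background on that array. The same bound was used for 4 genes without a symbol whose probe was dim on most mock arrays or on all later ones, and for PLT1 and IAA33, dim on most gamma arrays. For AT4G22960, 1 of these 4, the bound equals the measured fold. The bounds hold for the processed signal only. With normexp background correction the changes were smaller, for DRM1 a log2 of 1.26 against a bound of 3.465. The offset of 50 added there to every signal shrinks changes of dim genes by construction, so normexp cannot tell their true size.

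The choices of fit, gene lists, named genes and alternatives were made before the data were examined. Named genes were the 6 highest and 6 lowest log2 changes with a locus code and a symbol among genes past the threshold with the same sign in all 5 experiments. To these came the 2 members of each list with the smallest adjusted p, or 4 for DNA damage signalling, double-strand break repair, and G2 and mitosis. The values of 1 gene that the rule names are not reported here, though it is counted. The 17 lists held 319 genes, 312 of them on the array; ATM, ANAC044, SMR5, RAD9, PARP3, REV3 and DHAR1 matched no probe. They covered DNA damage signalling and checkpoint, double-strand break repair, excision, mismatch and translesion repair, G2 and mitosis, S phase and DNA replication, core histones, antioxidants and glutathione transferases, flavonoid and anthocyanin synthesis, photosynthesis and leaf senescence. They also covered salicylate and pathogen defence, jasmonate, abscisic acid and dehydration, heat shock, the circadian clock as a check on harvest time, root-expressed markers, and shoot meristem and stomatal lineage markers. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and members were counted both over all genes tested and adjusted over the list alone. Differences between experiments were tested with limma's F-test, and the response in experiments 3 to 5 was set against that in experiments 1 and 2 with an interaction term.

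The procedure was tested on simulated data for 23660 genes. Of changes of 0.5, 1 and 2 on the log2 scale, 44.8%, 80.6% and 93.9% were called, all in the right direction, and 4 of 150 calls were false. With no simulated effect, 0 of 17 lists, 0 genes in the F-test and 0 interactions were called. The simulated genes varied independently of each other. In the real lists the estimated correlation ranged from -0.06 for shoot and stomatal markers to 0.79 for flavonoids, with 0.68 for G2 and mitosis. The simulation thus does not test the list calls for members that vary together, and other exchanges of real arrays within pairs called up to 11 lists.

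The alternatives were a fit without the block, the experiment as a random block, normexp background correction with an offset of 50, quantile normalisation, scaling to the array median, the deposited table, no filter, a filter on all 10 arrays, the mean of a gene's probes, an intensity trend with a robust prior, stricter thresholds, and leaving out each experiment in turn. For lists, camera with an estimated correlation and limma's fry were added. The normexp alternative used the median spot signal in place of the planned mean spot signal, a column not used here. Each slide held the 2 arrays of 1 experiment and was scanned with it, so slide and scan are the same block as the experiment. Mock was always at the same place on its slide and gamma at another.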

Results

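Transcript levels were measured with 1-colour arrays in 14-day-old Arabidopsis seedlings, 24 h after 200 Gy of gamma radiation or a mock treatment. The experiment was run 5 times with independent plants, and each run gave 1 mock and 1 gamma array, so that each group held 5 arrays. On each array 71.7% to 76.6% of 43603 probes were well above background, and the signal at the 75th percentile lay between 1644.5 and 2641. The number of arrays limits the precision of the values given here.

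The main comparison asked which transcripts of the seedling respond to gamma rays. The 6 strongest named increases included 3 genes of the DNA damage and repair lists. SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, rose 52.9-fold (log2 5.73 ± 0.13 SE, n = 5 pairs, limma with Benjamini-Hochberg adjusted p = 6.41e-05). PARP2 (AT4G02390), a poly(ADP-ribose) polymerase that senses DNA breaks, rose 15.5-fold (log2 3.95 ± 0.12 SE), and the transcription factor ANAC103 (AT5G64060) rose 12.6-fold (log2 3.66 ± 0.15 SE). GEX1 (AT5G55490), a nuclear membrane protein of gametes and embryos, was not well above background on any mock array and rose at least 40.9-fold (adjusted p = 0.000319). The cytochrome P450 gene CYP96A11 (AT4G39500) rose at least 14.1-fold and the DNA methyltransferase gene DRM1 (AT5G15380) at least 11.04-fold, likewise against mock arrays not well above background.

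The strongest named decreases were smaller. CASP5 (AT5G15290), a membrane protein of the Casparian strip, was 3.88-fold lower after gamma irradiation (log2 -1.96 ± 0.24 SE, n = 5 pairs, limma adjusted p = 0.0145). RGF2 (AT1G13620), a root meristem growth factor, was 3.05-fold lower (-1.61 ± 0.24 SE), and the calmodulin-binding protein gene IQD16 (AT4G10640) fell by 1.62 ± 0.14 SE on the log2 scale. PLT1 (AT3G20840), a transcription factor of the root stem cell niche, was at least 2.40-fold lower (adjusted p = 0.0313) and the auxin response gene IAA33 (AT5G57420) at least 2.56-fold lower (adjusted p = 0.0171), both against gamma arrays that were mostly not well above background. XTH21 (AT2G18800), a cell wall enzyme, fell by 1.75 ± 0.22 SE with the brighter of its probes, while its other probe gave 0.33 ± 0.45 SE. On the gamma arrays these genes were dim: IQD16 and XTH21 were well above background on 4 of 5, CASP5 and RGF2 on 3, IAA33 on 2 and PLT1 on 1. Without the block CASP5, XTH21 and PLT1 did not pass (limma adjusted p = 0.157, 0.473 and 0.0545). Calls were also lost without experiment 3 or 4 for CASP5, 3, 4 or 5 for XTH21, 1, 3 or 5 for PLT1, 1, 3, 4 or 5 for RGF2 and 1 or 3 for IAA33, with adjusted p of at most 0.108.

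In all, 949 of 23666 genes (4.01%) passed the threshold in limma. Of these 398 rose and 551 fell, with median log2 changes of 0.61 and -0.54. Which direction held more genes depended on the settings: 520 rose and 495 fell with scaling to the array median, 518 and 494 with the deposited table, 175 and 153 without a filter, and 107 and 35 without the block. More also rose than fell without experiment 1 (148 and 118), 3 (115 and 77), 4 (113 and 68) or 5 (127 and 105). At least 2-fold changes were found in 114 genes that rose and 72 that fell, and at least 4-fold changes in 50 and 1. An unadjusted p under 0.05 in limma was reached by 5197 of the 23666 genes. Counts of list members at such a p, given below, are to be read beside that share. Each of the 949 genes moved in the same direction in 5 of 5 experiments, which a call with 5 pairs nearly requires and which is no separate support. Of all genes tested 23.7% did so, where chance gives 6.25%. The count fell to 142 without the experiment as a block, and to 266, 192, 181 and 232 without experiments 1, 3, 4 and 5, while 1021 genes passed without experiment 2. With normexp the log2 changes of dim genes shrank but stayed past the threshold, to 2.97 for GEX1, 1.52 for CYP96A11, 1.26 for DRM1, 2.79 for ANAC103, -0.89 for CASP5, -0.85 for XTH21, -0.84 for IQD16, -0.51 for PLT1, -0.67 for RGF2 and -0.65 for IAA33. The added offset of 50 makes such changes shrink by construction.

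**Figure D1:**
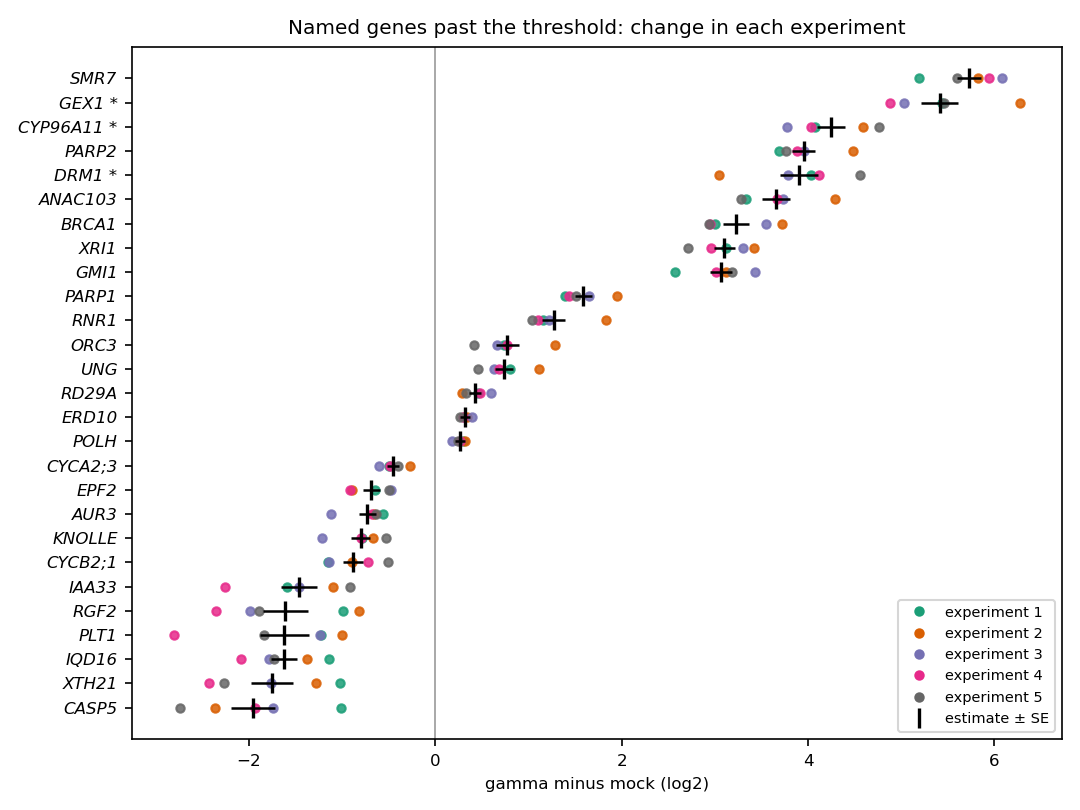
Gamma minus mock on the log2 scale (x axis) for 27 named genes that passed the threshold (y axis); points are the 5 experiments by colour and black marks with bars are the limma estimates ± SE. Asterisks mark genes not well above background on any mock array, whose plotted values rest on mock signals at background, and those of PLT1 and IAA33 rest mostly on gamma signals at background. SMR7 lies highest at 5.73 and CASP5 lowest at -1.96, and for each gene all 5 experiments lie on the same side of 0, as a call nearly requires.

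Genes of DNA damage signalling and the checkpoint rose together: 12 of the 14 measured rose and 0 fell, with a median log2 change of 2.15 over the list. The same 12 passed when adjusted over the list alone. XRI1 (AT5G48720), a gene named for its induction by X-rays, rose 8.59-fold (log2 3.1 ± 0.11 SE, n = 5 pairs), and GMI1 (AT5G24280), named for induction by gamma rays and mitomycin C, rose 8.38-fold (3.07 ± 0.12 SE). The ribonucleotide reductase subunit TSO2 rose by a log2 of 2.58 ± 0.16 SE, the cyclin CYCB1;1 by 2.29 ± 0.14 SE and the checkpoint kinase WEE1 by 0.78 ± 0.12 SE. SOG1, the transcription factor that heads this response, gave -0.14 ± 0.06 SE and the kinase ATR gave 0.01 ± 0.11 SE, neither past the threshold. The list was called upward by camera (adjusted p = 1.23e-17, median above 0 in 5 of 5 experiments), with adjusted p = 0.11 with an estimated correlation.

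Of the 23 double-strand break repair genes measured, 10 rose, 0 fell and 13 did not pass. Adjusted over the list alone, 11 rose and 1 fell, MRE11. BRCA1 (AT4G21070) rose 9.38-fold (log2 3.23 ± 0.14 SE, n = 5 pairs, limma adjusted p = 0.000431). PARP1 (AT2G31320) rose 3.005-fold (1.59 ± 0.09 SE, adjusted p = 0.00112). The end-joining genes KU70 (-0.03 ± 0.06 SE) and KU80 (0.03 ± 0.05 SE) and the break sensor MRE11 (-0.29 ± 0.08 SE) did not pass over all genes. Camera called the list upward (median 0.20, mean 0.97, adjusted p = 1.12e-09, median above 0 in 5 of 5 experiments), with adjusted p = 0.33 with an estimated correlation.

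Of 15 genes of excision, mismatch and translesion repair 2 rose and 0 fell, or 5 and 0 adjusted over the list alone. The uracil glycosylase UNG (AT3G18630) rose 1.67-fold (log2 0.74 ± 0.10 SE, n = 5 pairs, limma adjusted p = 0.0186) and the translesion polymerase POLH (AT5G44740) rose 1.201-fold (0.26 ± 0.05 SE, adjusted p = 0.0458). Camera called the list upward (median 0.04, adjusted p = 0.0316, median above 0 in 5 of 5 experiments), with adjusted p = 0.35 with an estimated correlation. The call ended without experiment 1 (adjusted p = 0.0856) or 2 (0.0786), and the median was 0.13 without experiment 4 and 0.086 without 5. POLH lost its call without any 1 of the 5 experiments, without the block and with normexp, and UNG lost it without experiment 1, 3 or 4 (adjusted p up to 0.0742 in limma).

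Genes of G2 and mitosis were lower after irradiation: 13 of 28 fell, 0 rose and 15 did not pass, and 23 fell adjusted over the list alone. The mitotic cyclin CYCB2;1 (AT2G17620) fell by 0.88 ± 0.11 SE on the log2 scale (n = 5 pairs, limma adjusted p = 0.0148). The cytokinesis syntaxin KNOLLE (AT1G08560) fell by 0.80 ± 0.10 SE (adjusted p = 0.0164), the Aurora kinase AUR3 (AT2G45490) fell by 0.73 ± 0.09 SE (adjusted p = 0.0153) and the cyclin CYCA2;3 (AT1G15570) fell by 0.45 ± 0.06 SE (adjusted p = 0.0215). The kinase CDKB1;1 was the 1 member above 0, at 0.13 ± 0.11 SE, and did not pass. The B-type cyclin CYCB1;1, which rose by 2.29 ± 0.14 SE, was placed in the DNA damage list and is not counted here. The list median was -0.59, below 0 in 5 of 5 experiments and between -1.13 and -0.37 in single experiments, and camera called it downward (adjusted p = 6.68e-14), with adjusted p = 0.33 with an estimated correlation. The list of shoot meristem and stomatal lineage markers was lower as well, with a median of -0.15, below 0 in 5 of 5 experiments (camera adjusted p = 0.0116, and adjusted p = 0.33 with an estimated correlation). The calls of CYCB2;1, KNOLLE, AUR3 and CYCA2;3 were lost without the block, at adjusted p = 0.43, 0.25, 0.18 and 0.31 in limma. They were also lost without experiment 1, 3 or 4 for CYCB2;1, 1 or 4 for KNOLLE, 4 or 5 for AUR3 and 1, 3, 4 or 5 for CYCA2;3, with adjusted p of at most 0.089.

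Of 29 genes of S phase and DNA replication 3 rose, 0 fell and 26 did not pass, and 11 rose adjusted over the list alone. RNR1 (AT2G21790), the large subunit of ribonucleotide reductase, rose 2.41-fold (log2 1.27 ± 0.12 SE, n = 5 pairs, limma adjusted p = 0.00742) and the origin recognition subunit ORC3 (AT5G16690) rose 1.71-fold (0.77 ± 0.12 SE, adjusted p = 0.0296). ORC3 lost its call without the block (limma adjusted p = 0.0642) and without experiment 1, 3, 4 or 5 (up to 0.102). The list median was 0.30, above 0 in 5 of 5 experiments, and camera called it upward (adjusted p = 5.47e-10), with adjusted p = 0.33 with an estimated correlation. Core histone genes did not pass in either direction: 0 of 21 in limma, with 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The lowest adjusted p there was that of HTA13 (AT3G20670), at -0.31 ± 0.07 SE (adjusted p = 0.061, lower in 5 of 5 experiments), and the histone H3.1 gene AT5G65360 gave 0.26 ± 0.07 SE. The histone list had a median of -0.03 and a mean of -0.0017, while camera's direction was upward (adjusted p = 0.93).

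**Figure D2:**
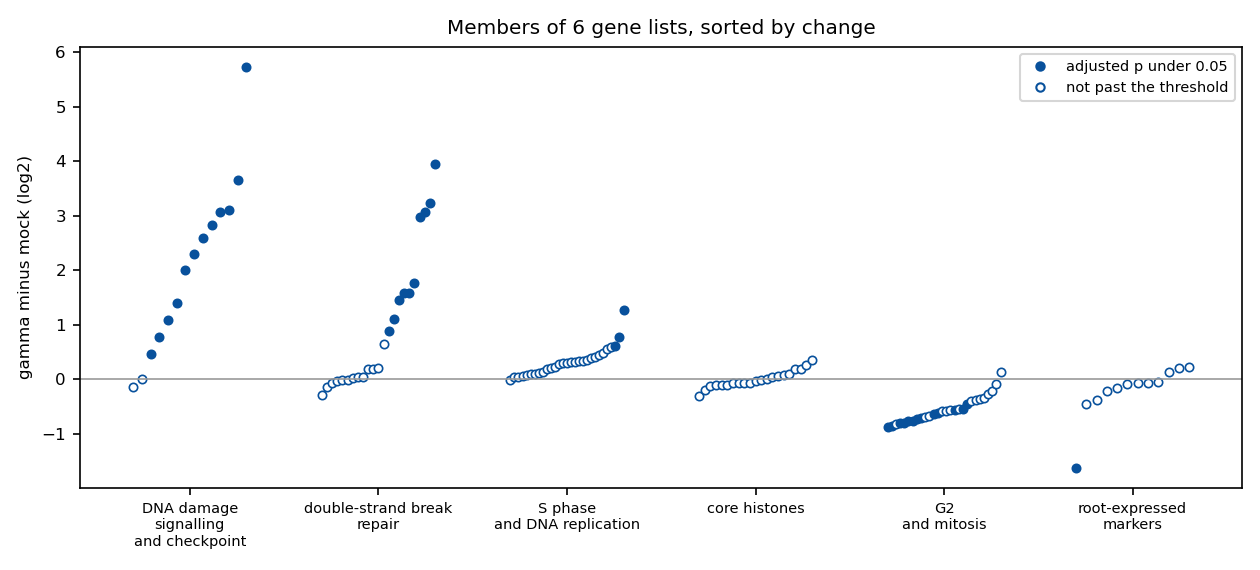
Gamma minus mock on the log2 scale (y axis) for each measured member of 6 gene lists (x axis), sorted within the list; filled points passed the threshold in limma and open points did not. Members of the DNA damage list reach 5.73, 27 of 28 members of the G2 and mitosis list lie below 0, and core histones lie between -0.31 and 0.35. The cyclin CYCB1;1, at 2.29, is plotted in the DNA damage list and not with G2 and mitosis.

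Lists of oxidative stress and secondary metabolism held no gene past the threshold. Among 28 antioxidant and glutathione transferase genes 0 passed in limma, also adjusted over the list alone. At an unadjusted p under 0.05 there were 5, where 5197 of all 23666 genes reached such a p. The zinc finger gene ZAT10 (AT1G27730) gave 0.60 ± 0.19 SE and the glutathione peroxidase gene GPX6 (AT4G11600) 0.25 ± 0.08 SE. Camera called the list upward (median 0.10, adjusted p = 0.0316, median above 0 in 5 of 5 experiments), with adjusted p = 0.33 with an estimated correlation. Among 21 flavonoid and anthocyanin genes 0 passed in limma, also adjusted over the list alone, with 1 at an unadjusted p under 0.05. Their estimates were all above 0, with DFR (AT5G42800) at 0.54 ± 0.20 SE and chalcone synthase, CHS (AT5G13930), at 0.50 ± 0.23 SE. Camera called that list upward (median 0.36, adjusted p = 0.00254), with adjusted p = 0.66 with an estimated correlation. Its medians were 0.08, 1.45, 0.45, -0.42 and 0.20 in experiments 1 to 5, so that 4 of 5 were above 0, and without experiment 2 the median was 0.05 and the call ended (adjusted p = 0.31), while without experiment 4 the median was 0.59. The antioxidant call ended without experiment 2 (median 0.044, adjusted p = 0.0786) or 3 (0.0814), without the block (0.065) and with quantile normalisation (0.115).

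Of 14 abscisic acid and dehydration genes 2 rose, 0 fell and 12 did not pass, and 4 rose adjusted over the list alone. The dehydration gene RD29A (AT5G52310) rose 1.35-fold (log2 0.43 ± 0.06 SE, n = 5 pairs, limma adjusted p = 0.0252) and the dehydrin ERD10 (AT1G20450) rose 1.25-fold (0.32 ± 0.05 SE, adjusted p = 0.0272). Camera called the list upward (median 0.24, or 0.16 without experiment 2, adjusted p = 0.00135, median above 0 in 5 of 5 experiments), with adjusted p = 0.33 with an estimated correlation. The calls of RD29A and ERD10 both ended without the block (adjusted p = 0.9996 each in limma) and without experiment 1, 3, 4 or 5, with adjusted p up to 0.099 and 0.126.

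For 11 salicylate and pathogen defence genes, 14 jasmonate genes, 14 heat shock genes and 9 leaf senescence genes, 0 passed in limma, also adjusted over each list alone, with 0, 3, 1 and 3 at an unadjusted p under 0.05. The salicylate list had a median of 0.15 (camera adjusted p = 0.156), with WRKY40 at 0.47 ± 0.24 SE and EDS1 at 0.17 ± 0.09 SE. The jasmonate list had a median of 0.13 (adjusted p = 0.0723), with the repressor gene JAZ5 at 0.50 ± 0.18 SE and the lipoxygenase gene LOX2 at 0.28 ± 0.10 SE. The heat shock list had a median of -0.06 (adjusted p = 0.385), with HSP18.2 at -0.22 ± 0.09 SE and HSP23.6 at -0.67 ± 0.37 SE, and its medians ranged from -1.65 in experiment 1 to 0.59 in experiment 2. The senescence list had a median of -0.18 (adjusted p = 0.925), with WRKY53 at 0.68 ± 0.17 SE and NAP at -0.19 ± 0.06 SE. The salicylate list was called without experiment 5 (median 0.16, adjusted p = 0.0219) and the jasmonate list without experiment 3 (median 0.19, adjusted p = 0.0497).

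Photosynthesis genes did not pass: 0 of 31 in limma, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The oxygen-evolving protein gene PSBO2 gave 0.14 ± 0.06 SE and the antenna protein gene LHCB4.2 -0.15 ± 0.07 SE. The list median was -0.0079 and the mean -0.0021, while camera's direction was upward (adjusted p = 0.733); without experiment 2 the list was called upward (median 0.04, adjusted p = 0.0413). Among 11 circadian clock genes, chosen as a check on the time of harvest, 0 passed in limma, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. ELF4 gave 0.21 ± 0.15 SE and PRR7 -0.11 ± 0.09 SE. The clock list had a median of -0.04 and a mean of -0.06, with camera's direction upward (adjusted p = 0.762). Its estimates were above 0 for 5 genes and below 0 for 6, the lowest that of LHY at -0.43 ± 0.73 SE. A median and a directional test cannot show a shift that raises some clock genes and lowers others. With some SEs this wide, a difference in the time of harvest was not excluded.

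Among 12 root-expressed markers 1 fell, PLT1, and 11 did not pass, with 2 that fell adjusted over the list alone. CASP1 (AT2G36100), another Casparian strip gene, gave -0.45 ± 0.12 SE (limma adjusted p = 0.0967, lower in 5 of 5 experiments). The root list had a median of -0.08 (camera adjusted p = 0.133), below 0 in 4 of 5 experiments, and was called downward without experiment 2 (median -0.21, adjusted p = 0.0090). Among 11 shoot meristem and stomatal lineage markers 1 fell and 0 rose, with 5 that fell adjusted over the list alone. EPF2 (AT1G34245), a peptide that limits stomatal density, fell by 0.68 ± 0.09 SE on the log2 scale (n = 5 pairs, limma adjusted p = 0.0169), and MUTE (AT3G06120) gave -0.41 ± 0.11 SE. EPF2 lost its call without the block (limma adjusted p = 0.762) and without experiment 1, 3, 4 or 5 (up to 0.0657). Camera called this list downward (median -0.15, adjusted p = 0.0116, median below 0 in 5 of 5 experiments), with adjusted p = 0.33 with an estimated correlation and 0.065 without the block.

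Of the 17 lists, 9 were called with camera's preset correlation, 7 upward and 2 downward. With an estimated correlation 0 were called, with 2 at an unadjusted p under 0.05, and fry called 4: DNA damage signalling, double-strand break repair, G2 and mitosis, and the shoot and stomatal markers. Of the 28 named genes past the threshold, 12 lost their call without the block and 15 lost it on leaving out at least 1 of the 5 experiments, while their folds moved by at most 1.27 times. Without experiments 1 to 5 in turn, 16, 29, 15, 15 and 18 of the 48 named genes passed.

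**Figure D3:**
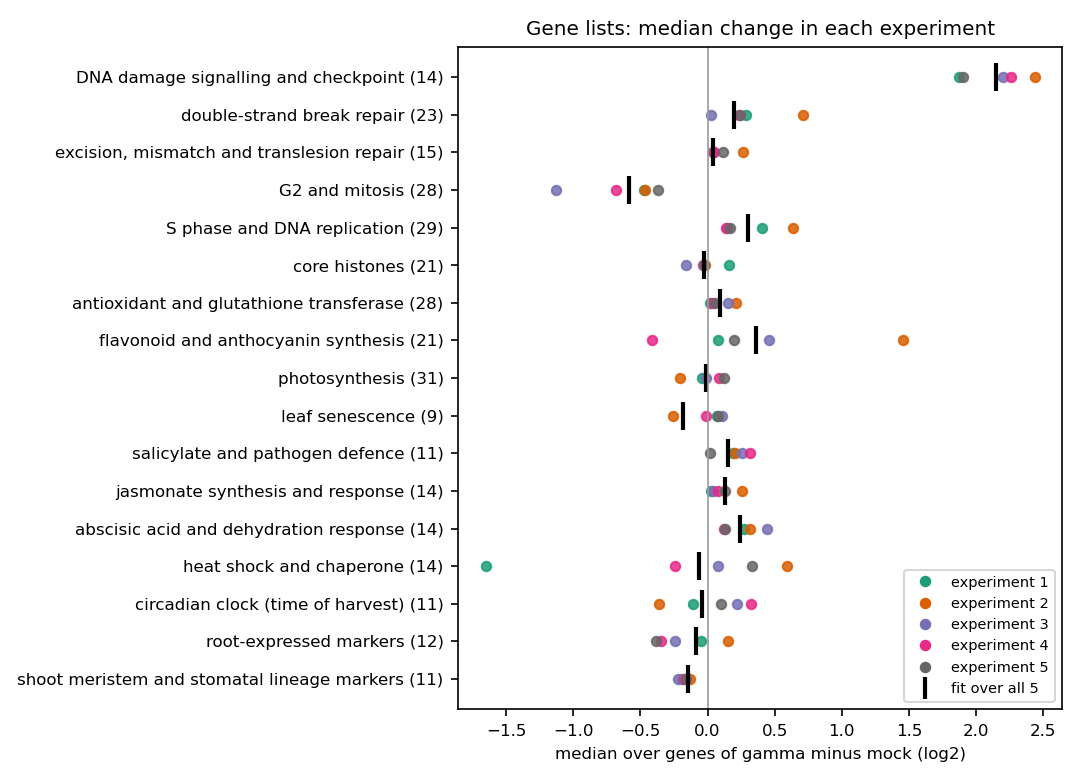
Median over the members of each gene list of gamma minus mock on the log2 scale (x axis), with the number of genes measured in brackets (y axis). Coloured points are the 5 experiments and black marks are medians of the limma estimates; the DNA damage list lies between 1.87 and 2.44 in all 5, while the flavonoid list spans -0.42 to 1.45 and the heat shock list -1.65 to 0.59.

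The arrays of separate experiments were then compared, to set the size of the irradiation response beside that of the run. The experiment accounted for 77% of the variance over all genes, irradiation for 11.5% and the residual for 11.5%. In limma's F-test 13305 genes (56.2%) differed between experiments after adjustment, and 6118 of all genes had a range of at least 2-fold between experiments. The first principal component held 36.9% of the variance between arrays and the fourth 10%. The changes of all genes had an SD of 0.38, 0.58, 0.43, 0.39 and 0.35 in experiments 1 to 5, and across genes, which are not independent replicates, the changes of pairs of experiments correlated with r from 0.22 to 0.63.

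**Figure D4:**
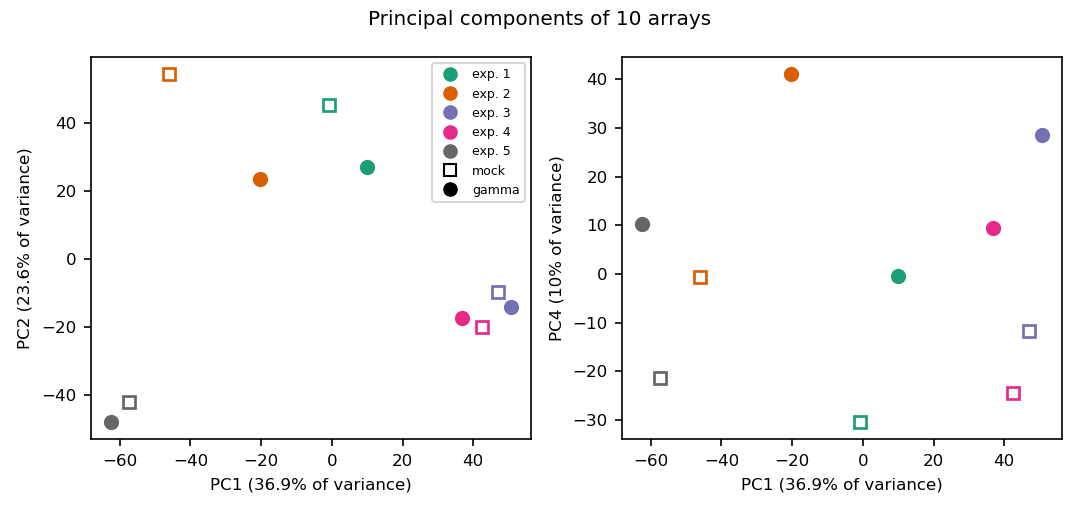
Principal components of the 10 arrays, with the second (left) and the fourth (right) against the first; axes give the share of variance, colours the experiment, squares mock and circles gamma. The first component holds 36.9% of the variance and the fourth 10%.

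Because 2 experiments were run in an earlier year than the other 3, the response was compared between them. A transcript with the array identifier TC379423, named here after its value was seen, was the 1 gene past the threshold (limma adjusted p = 0.00944, higher after irradiation in 5 of 5 experiments). It was well above background on both earlier mock arrays and on 0 of the 3 later ones, so the later rise is given as a bound: 8.46-fold in the earlier and at least 74.96-fold in the later experiments. With normexp the difference was 0.62 ± 0.32 SE on the log2 scale and did not pass (adjusted p = 0.565), nor did it with quantile normalisation (adjusted p = 0.0905). The offset of 50 in normexp shrinks this difference by construction, since the later mock signals were dim. In all, 2486 genes had an unadjusted p under 0.05 for this difference. Leaving out experiment 3, 4 or 5 left 0 genes past the threshold. Leaving out experiment 1 or 2 left a single earlier experiment, so no count is given for these.

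By list, 8 of 17 differed between the earlier and later experiments with camera's preset correlation. The S phase list had a median of 0.52 in the earlier and 0.13 in the later experiments (adjusted p = 2.18e-07), the G2 and mitosis list -0.45 and -0.69 (0.017), the double-strand break list 0.35 and 0.11 (0.0217) and the core histones 0.01 and -0.09 (0.011). Photosynthesis genes had medians of -0.12 and 0.07 (adjusted p = 1.56e-05), flavonoid genes 0.73 and 0.08 (0.000307), root-expressed markers 0.04 and -0.36 (0.0002) and clock genes -0.14 and 0.17 (0.0349). With an estimated correlation 0 of the 17 differed, with 0 at an unadjusted p under 0.05, and adjusted p = 0.668 or more for these 8. The DNA damage list did not differ in this test, with medians of 2.16 and 2.14 (adjusted p = 0.632).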

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

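The tests of probes at other spots, of place on the slide, of dividing cells, root share and scaling, and the tests of gene lists between the earlier and later experiments were chosen only after the results were seen.

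In 8 of 172 groups of 5 values (4.65%), 1 value stood far from the others, where chance gives about 1 in 20. DRM1 was at -3.65 on gamma array 2, against -4.57 to -4.34 on the others. PARP1 was at -1.82 on mock array 2, against -1.62 to -1.54. KNOLLE was at 1.38 on mock array 1, against 0.58 to 0.76. LHCB4.2 was at 5.77 on gamma array 1, against 6.20 to 6.30. CASP1 was at 1.57 on mock array 3, against 0.72 to 0.89. The change of AUR3 was -1.12 in experiment 3, against -0.68 to -0.56. The change of RNR1 was 1.84 in experiment 2, against 1.04 to 1.22. On mock array 5, 76.3% of probes were well above background, against 71.7% to 73.0%.

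Between the earlier and later experiments, the measured response of TC379423 differed by 3.66 on the log2 scale in the interaction test. That size is not exact, since the later mock signals were at background, and with normexp it was 0.62 ± 0.32 SE and did not pass (limma adjusted p = 0.565). The offset of 50 in normexp shrinks such a difference by construction, so the normexp value cannot decide whether the response differed. By camera with its preset correlation, the medians of 8 lists differed, later minus earlier, by -0.23 for double-strand break repair, -0.24 for G2 and mitosis, -0.39 for S phase, -0.11 for core histones, -0.65 for flavonoids, 0.19 for photosynthesis, 0.31 for the clock and -0.40 for root markers. None of the 8 differed with an estimated correlation, where 0 lists had an unadjusted p under 0.05.

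Splits of the arrays did not exclude chance as the origin of the 949 changed genes by the share alone: 6 of 100 splits drawn gave as many, the real one included, and the highest other gave 956. The 5 others all parted the pair of experiment 2 and no other pair, and apart from them the highest count was 25. With the experiment as a block, these 5 are the same comparison, the change within experiment 2. They are thus 1 test drawn 5 times, and it holds that experiment's own gamma and mock arrays. Shares of the 100 splits, for genes and for lists, therefore count repeated tests and are not chance rates. Among the 16 exchanges of arrays within pairs the real one gave 949 and the highest other 0, and 16 exchanges are too few for a share under 0.05. For the 9 lists called, 11 of 100 splits gave as many, the highest other 11. Among the exchanges within pairs the highest other also called 11 lists, so chance was not excluded. By list, and again not as chance rates, as small a p came in 1 of 100 splits for DNA damage and for double-strand breaks, 4 for excision repair, 5 for shoot markers, 8 for S phase, 12 for G2 and mitosis, 15 for abscisic acid, 17 for antioxidants and 51 for flavonoids. Within pairs it came in 1, 1, 2, 1, 2, 1, 2, 3 and 11 of the 16 exchanges. Other probes of the called genes, at other spots, went the same way in 99% of cases and those of genes not called in 83.8%, where differences local to spots give about 50%, which argues against such differences but says nothing of irradiation, while handling tied to place on the slide cannot be told apart from irradiation, since all 5 slides held mock and gamma at the same places.

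The median of G2 and mitosis genes was below 0 in 5 of 5 experiments, that of S phase genes above 0 in 5 of 5, and that of core histones lay between -0.16 and 0.16, below 0 in 4 of 5. The median of core histones exceeded that of G2 and mitosis by 0.607 (SD 0.239 over 5 experiments, exact sign-flip p = 0.0625). This argues against an even loss of cells that express both lists as the whole cause. It cannot tell whether fewer cells divided while others still replicated DNA, since histone genes need not fall then. Shoot meristem and stomatal lineage markers were lower too (median -0.15, below 0 in 5 of 5, camera adjusted p = 0.0116, 0.33 with an estimated correlation, fry adjusted p = 0.00273), so a smaller share of such cells stays open as a part of the cause. Root markers exceeded the G2 and mitosis genes by 0.450 (SD 0.335, above 0 in 4 of 5 experiments, -0.015 in experiment 5, exact sign-flip p = 0.125). This argues only weakly against a smaller share of the whole root as the whole cause. The list median does not test a smaller share of the root meristem alone, which stays open, with PLT1 and RGF2 among the strongest named decreases. The highest median of the G2 and mitosis list under another scaling or background correction was -0.46, which argues against the scaling of the arrays. A lower expression of mitotic genes in cycling cells, as a checkpoint response, is a candidate explanation that was not tested, and handling tied to place on the slide stays open here too.

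The mean of the S phase list medians was 0.372 higher in the earlier than in the later experiments, a difference that camera called at its preset correlation but not with an estimated one (p = 0.142, adjusted p = 0.668). That was the largest difference in 1 of 10 splits of the 5 experiments, the highest other 0.261, and 10 splits are too few for a share under 0.05. A wider spread of all changes in the earlier experiments is argued against by the scaled medians, whose lowest earlier value lay 0.594 above the highest later one (SD of the later 0.0711). For the list median, experiment 2 alone is argued against by experiment 1, which lay 0.239 above the highest later one (SD 0.0136), though this rests on 1 experiment. For RNR1 and ORC3 experiment 1 did not lie above all the later ones, at 1.16 and 0.74. Their later changes were 1.04 to 1.22 and 0.41 to 0.76, and only experiment 2 stood apart, at 1.84 and 1.28. Differences of growth, reagents or dose between the years stay open, and no biological explanation was tested.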

How the results depend on the processing

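No alternative was added after the data were seen. Scalings moved the median of all genes by under 0.1. Without the replicate block that pairs the arrays of an experiment, 142 genes passed, all of them among the 949, and 16 of the 48 named genes; with the experiment as a random block 1919 passed, 870 of them shared. Without a filter 328 of 34290 genes tested passed, 306 of them shared. At an adjusted p under 0.01 158 passed, and 186 changed at least 2-fold. Leaving out 1 experiment gave 181 to 1021 genes and 15 to 29 named genes, with fewer arrays. The other alternatives gave 917 to 1157 genes, with more that fell than rose except with the array median (520 rose, 495 fell) and the deposited table (518 and 494). Between experiments 18375 genes differed without a filter, and 12708 to 14424 with normexp, quantile normalisation, the deposited table and all 10 arrays above background. No named gene turned its direction: of their comparisons 414 kept their side of the threshold, 62 fell below it and 4 passed it.

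The difference between earlier and later experiments gave 46 genes with normexp, 2 with quantile normalisation, 17 with the deposited table, 0 without a filter (2561 at an unadjusted p under 0.05 in limma), 13 with all 10 arrays above background, and 0 to 617 on leaving out 1 experiment. Without experiment 1 a single earlier experiment remained, assumed to vary like the others, and gave the 617, TC379423 among them; the 0 came without experiments 2 to 5, with 1420 to 2332 at an unadjusted p under 0.05.

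Of the 9 lists called, 0 remained with an estimated correlation and 4 with fry. With an estimated correlation the medians stay as they were by construction and the test has the arrays' 4 residual degrees of freedom: 2.15 for DNA damage, 0.20 for double-strand breaks, 0.041 for excision repair, -0.59 for G2, 0.30 for S phase, 0.10 for antioxidants, 0.36 for flavonoids, 0.24 for abscisic acid and -0.15 for shoot markers. With fry excision repair (0.041, adjusted p = 0.0603), S phase (0.30, 0.0624), antioxidants (0.10, 0.0766), flavonoids (0.36, 0.497) and abscisic acid (0.24, 0.0603) did not pass. Antioxidants lost their call without the block (0.10, adjusted p = 0.065), with a random block (0.10, 0.141) and with quantile normalisation (0.074, 0.115), and shoot markers (-0.15) without the block and with a random block. Jasmonate genes gained a call without a filter (0.13, adjusted p = 0.0267) and with the mean of probes (0.16, 0.0379). The block ended no other list call.

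Lists not called with the main settings turned the direction of their test. Core histones did so with normexp (-0.039), quantile normalisation (-0.053), fry (-0.029) and without experiment 1 (-0.052). Senescence did so without the block, with a random block and with the mean of probes (-0.18 each), and without experiment 2 (0.064). Photosynthesis did so without experiments 4 (-0.034) and 5 (-0.043), heat shock without experiment 1 (0.14) and the clock without experiment 3 (-0.044).

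On leaving out 1 experiment, medians ranged from 0.030 to 0.13 for excision repair, -0.052 to -0.011 for core histones, 0.044 to 0.10 for antioxidants, 0.054 to 0.59 for flavonoids, 0.16 to 0.30 for abscisic acid, -0.043 to 0.041 for photosynthesis, -0.22 to 0.064 for senescence, 0.067 to 0.16 for salicylate, 0.10 to 0.19 for jasmonate, -0.22 to 0.14 for heat shock, -0.044 to 0.12 for the clock and -0.21 to -0.081 for root markers. Apart from fewer arrays, the cause was not tested. No block by slide or scan was run apart from the experiment, since they are the same. Signal over background limits the dim genes, whose log2 changes shrink with normexp, as its added offset of 50 requires.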

Other observations

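The genes and families here were chosen after their values were seen. Several genes with a locus code but no symbol gave large increases, each higher in 5 of 5 experiments, as their choice required. The probe of AT5G07610 was well above background on 1 of 5 mock arrays. Its mean rise over the 5 experiments was at least 196-fold (limma adjusted p = 0.00158), at 80.45-fold in the earlier and at least 355-fold in the later ones. That of AT4G25330 was well above background on 2 of 5. Its mean rise was at least 23.9-fold (adjusted p = 0.0165), at 8.31-fold in the earlier and at least 48.3-fold in the later experiments. AT4G22960, likewise on 2 of 5, rose 36.1-fold (adjusted p = 6.41e-05). That is the measured fold, since its bound was the same, and it rests on mock signals mostly not well above background. AT5G60250, on 5 of 5, gave a log2 change of 4.12 ± 0.20 SE (n = 5 pairs, limma adjusted p = 0.000661). AT4G25330 and TC379423 were above background on both earlier mock arrays and on 0 of the 3 later ones, with mean mock levels of -4.97 and -8.79 for AT4G25330 and -4.43 and -8.61 for TC379423. Their gamma levels lay closer together, at -1.92 and -2.50 for AT4G25330 and -1.35 and -1.87 for TC379423. Among other genes that rose were MND1, known from meiotic recombination, by 1.45 ± 0.10 SE and AT1G13330, which shares the symbol AHP2 and encodes the partner of MND1, by 2.41 ± 0.14 SE.

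Of 422 gene families grouped by symbol, each with at least 5 members, camera called 10 at its preset correlation and 0 with an estimated correlation (adjusted p = 0.983 for each). All 10 kept their direction under every scaling tried. The calmodulin-binding IQD family had a median of -0.15, with 24 of 31 members lower, and 5 fell: IQD16, IQD12 (-0.67), IQD6 (-0.62), IQD26 (-0.45) and IQD33 (-0.38). The auxin-induced SAUR family had a median of -0.26 and all 14 members below 0, though 0 passed in limma and its median in experiment 4 was 0.06. The genes grouped under the symbol MCM, which include MCM9 and MCM10 but not MCM7, had a median of 0.39. Of these, 7 of 7 were above 0 and 0 past the threshold. The arabinogalactan protein family AGP had a median of -0.14, with 21 of 27 members lower and 4 that fell (AGP31, AGP17, AGP22 and AGP7). Among the B-type cyclins, CYCB1;1 rose by 2.29 ± 0.14 SE while 4 others fell (CYCB2;1, CYCB1;2, CYCB2;4 and CYCB2;2).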
